A study of Mus musculus with 9 samples.

How the data were processed

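Poly(A) RNA of mouse brain was sequenced in 9 libraries, 3 each from wild-type mice given a control virus (WT), N171-82Q mice given the same control virus (HD) and N171-82Q mice given a WNT5B virus. Per the labels both viruses drive their cargo from a GFAP promoter, mCherry alone or WNT5B with mCherry. The series text places the injection in the striatum, and the labels give the tissue as brain without a region. The library kit named in the labels does not keep the strand, so reads from exons that overlap on both strands cannot be assigned by strand. Sex, age and the animal behind each library are not in the labels.

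The signal values were deposited by the authors as 1 decimal number per protein-coding gene and library. From the values themselves they are estimated read counts divided by 1 factor per library, with the 9 libraries scaled jointly and no division by gene length. Low values fall on multiples of 1 step per library for 97.47 to 98.53 percent of genes (tolerance 0.01), and that step, the value of 1 read, is 0.704 to 0.808 in WT, 0.616 to 0.797 in HD and 1.61 to 2.14 in WNT5B libraries. Per the submitters' processing notes the reads were aligned with STAR to mm10. The counting program, the annotation, the program that normalized the values and all versions are not given in the sources used here. All 21853 gene identifiers match protein-coding genes of GENCODE M21, which supplied symbols, positions, transcript lengths and exon overlaps, and 24 symbols occur more than once.

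Dividing by the step gives 67.8 to 77.8 M reads in WT, 69.8 to 90.6 M in HD and 37.3 to 52.1 M in WNT5B libraries. The summed values are 54.6 to 54.7, 55.6 to 55.8 and 79.9 to 83.8 M. Genes above 0 number 17027 to 17132, 17223 to 17349 and 14291 to 14588, and 3478 genes are at 0 in all 9 libraries. For genes with a mean of at least 100, the variance between replicates was 1.73 to 3.18 times that of counting reads in WT, 1.75 to 2.09 times in HD and 37.3 to 39.05 times in WNT5B libraries, and the median SD of log2 values was 0.046, 0.04 and 0.258. No mitochondrially encoded gene is in the files, and no gene of the sex-linked list passed the filter.

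A count model had been planned. Because the values are normalized decimals, they were tested on a log scale with limma 3.58.1 in R 4.3.3 instead. Genes with a value of at least 10 in at least 3 libraries were kept (15411). Log2 of the value plus 3, at the deposited scale, was fitted with a mean per group over all 9 libraries (6 residual degrees of freedom) and moderated with a trend of the variance on the mean. The added 3 shrinks the fold changes of low genes. Fold changes are differences of mean log2 values, so where replicates scatter they can be larger than the ratio of the means. The 3 contrasts were HD against WT, WNT5B against HD and WNT5B against WT, and a gene counts as changed at Benjamini-Hochberg adjusted p < 0.05 over all genes tested. Standard errors (SE) are those of the moderated fit.

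Of 37 gene lists, the 35 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with the estimated correlation and with fry, with adjusted p over the lists of a contrast. Members called over the list alone were adjusted within the list. The text names the genes of the study whatever their values, the 6 largest rises and 6 largest falls per contrast among called genes without overlap of replicates and with an average of at least 1 on the log2 CPM scale, and up to 4 members with the smallest p per list. Symbols of unnamed gene models were left out of the largest changes, and a few genes the rule selects are not reported here.

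The procedure was tested on simulated data with counts scattered like those of each group, in which 200 genes were changed by a known factor. For HD against WT it recovered 9.43, 39.62, 77.36 and 90.24 percent of genes changed 1.2-, 1.5-, 2- and 4-fold, with 0 false calls among 14928 unchanged genes. For WNT5B against HD it recovered 23.08, 54.9, 74.58 and 97.37 percent with 410 false calls among 14943 (2.74 percent), 247 of them at least 2-fold. With a weight per group the false calls were 17 and 11, which is why that count stands beside the main one. For HD against WT it then recovered 77.36 percent of genes changed 1.2-fold and 100 percent of those changed 1.5-, 2- or 4-fold. For WNT5B against HD it recovered 19.23, 47.06, 71.19 and 97.37 percent. Only 200 genes were changed in the simulation, while 6957 and 11942 were called in the data. The Benjamini-Hochberg limit admits larger p-values when more genes change. The rates of recovery and of false calls therefore need not hold for the data.

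Alternatives covered the scale, the filter, the added constant, the test, a replicate block, single libraries left out, groups of genes left out and removal of the transcript length and GC trend by a spline per library. The closing section gives their effect. Transcript length and GC content are those of the longest annotated transcript of each gene. Counts for overlapping genes, with over 10 percent of exon bases shared, are marked where such a gene is named for its size of change.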

Results

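In brain libraries of N171-82Q Huntington (HD) mice, microglia, oligodendrocyte and cortical excitatory neuron genes were lower than in libraries of wild-type (WT) mice. Striatal projection neuron genes were lower by a smaller amount. Both groups had received the control virus, an AAV that carries mCherry behind the astrocyte promoter GFAP (n = 3 libraries each). Cx3cr1, the fractalkine receptor of microglia, fell from 4765 ± 30.7 (mean ± SD of normalized read counts) to 588 ± 13.4, a log2 fold change of -3.01 (SE 0.06, adjusted p = 3.4e-08). Lcn2, the iron-binding lipocalin of reactive astrocytes and neutrophils, rose from 5.26 ± 2.27 to 1776 ± 31.7 (log2 7.79, SE 0.49, adjusted p = 7.0e-06). Of 15411 genes tested with limma (a moderated t test, Benjamini-Hochberg adjusted p < 0.05), 6957 changed, 3774 higher and 3183 lower in HD, and 1573 of them changed at least 2-fold (687 higher, 886 lower). With every library scaled to the same total, 51.3 percent of the changed genes were higher instead of 54.25, and with upper-quartile factors 46.13 percent, so the majority direction depends on the scale. With a weight per group in place of a shared spread 12779 genes passed, among them all 6957. The p-values measure only spread between libraries, because the labels do not say that the 3 libraries of a group came from separate animals. That spread was shared over all 9 libraries, so the scatter of the WNT5B libraries enters it. For genes with a mean of at least 100, the median SD of log2 values was 0.258 in WNT5B, 0.046 in WT and 0.04 in HD libraries. A gene not called in HD against WT can therefore reflect scatter of libraries outside this comparison. The variance between WT replicates was 1.73 to 3.18 times that of counting reads. Between HD replicates it was 1.75 to 2.09 times, and between a WT and an HD library 123.41 to 148.85 times. Repeated libraries of the same sample might differ as little as these replicates do. Whether the differences between HD and WT given here come from genotype or from the samples taken cannot be told. Gene lists and the rule for naming genes were set before the data were examined.

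The 6 largest rises in HD that met the naming rule were Lcn2, Maff, Dcst2, Wnt10b, Plin4 and Itgad. Maff, a small Maf transcription factor induced by stress, went from 29.1 ± 1.16 to 737 ± 48.6 (log2 4.53, SE 0.55, limma adjusted p = 2.5e-04), and Dcst2, a membrane protein needed for sperm-egg fusion, from 16.7 to 404 (4.42, adjusted p = 9.9e-06). Wnt10b, a ligand of canonical Wnt signalling, rose from 126 ± 6.08 to 2535 ± 27.2 (4.30, SE 0.12, adjusted p = 2.0e-07). Plin4, a lipid droplet coat protein, rose from 468 ± 27.7 to 9027 ± 199 (4.26, SE 0.07, adjusted p = 1.4e-08), and Itgad, an integrin alpha chain of leukocytes, from 14.5 to 321 (4.23, adjusted p = 2.2e-06). In mm10 (GENCODE M21) Lcn2 lies at chromosome 2, 32384633 to 32388252, Wnt10b at chromosome 15, 98770712 to 98778150 and Plin4 at chromosome 17, 56100591 to 56109803.

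Of the largest falls reported here, 3 were microglia genes. Fcrls, an Fc receptor-like scavenger receptor, went from 1303 ± 38.6 to 44.2 ± 5.59 (log2 -4.80, SE 0.28, limma adjusted p = 4.6e-06). Gpr34, a lysophosphatidylserine receptor, fell from 951 to 59.7 (-3.93, adjusted p = 1.1e-04), and Olfml3, a secreted matrix protein of microglia, from 1340.1 to 123 (-3.42, adjusted p = 2.6e-05). Hes5, a Notch target that holds back neurogenesis, went from 593 to 46.5 (-3.59, adjusted p = 2.5e-06), and Kctd21, an adaptor of cullin 3 ubiquitin ligase, from 1024 to 102 (-3.28, adjusted p = 0.00681). In mm10 Fcrls lies at chromosome 3, 87250758 to 87263738, Gpr34 at chromosome X, 13632089 to 13640858 and Cx3cr1 at chromosome 9, 119901616 to 120069879.

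**Figure D1:**
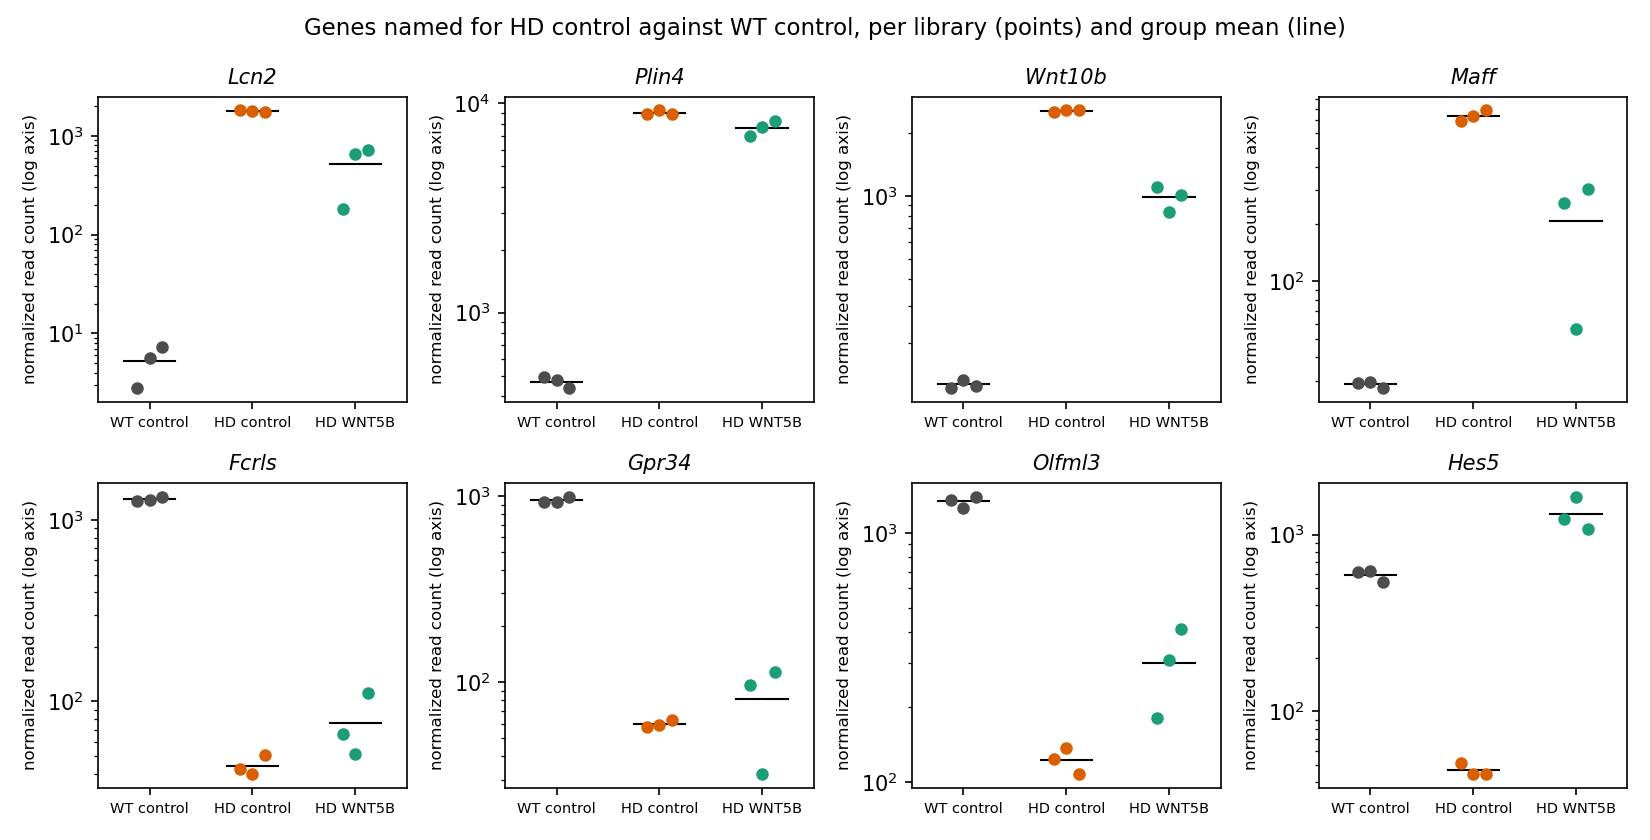
Normalized read counts of 8 genes in each of the 9 libraries on a log axis: Lcn2, Plin4, Wnt10b and Maff, which rose in HD, and Fcrls, Gpr34, Olfml3 and Hes5, which fell. Points are libraries (n = 3 per group) and lines are group means.

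Microglia genes gave the largest median fall of any tested list: 17 of 20 fell, 0 rose and 3 were not called, with a median log2 change of -1.91 (limma camera set test, Benjamini-Hochberg adjusted p = 6.2e-09, and 0.00883 with an estimated correlation between genes). P2ry12, the ADP receptor of microglial processes, fell by 2.63 (adjusted p = 3.4e-06), and Tmem119, a marker of resident microglia, fell by 2.51 (adjusted p = 4.3e-06). Adjusted over the list alone, 18 passed. The activated microglia list was not called (5 higher, 2 lower and 13 not called of 20, adjusted p = 0.522, 6 over the list alone). In that list Lgals3, a galectin of phagocytes, rose by 2.37 (adjusted p = 0.00153) and Trem2, a lipid-sensing microglial receptor, fell by 0.85 (adjusted p = 7.3e-04).

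Of 20 oligodendrocyte genes, 18 were lower in HD and 2 were not called (18 over the list alone, median -0.99, camera on the limma fit, adjusted p = 1.6e-10, and 0.00883 with an estimated correlation). The surface myelin protein gene Mog fell by 1.38 (adjusted p = 1.6e-06) and Mag, the myelin-axon adhesion protein, by 0.97 (adjusted p = 5.0e-07). Trf, the iron carrier transferrin, fell by 1.82 (adjusted p = 4.2e-08), with 63.49 percent of its exon bases shared with another gene. For oligodendrocyte precursors 8 of 15 genes fell, 0 rose and 7 were not called (8 over the list alone, median -0.56, adjusted p = 0.00343; adjusted p = 0.144 with an estimated correlation). Bcas1, a marker of early myelinating cells, fell by 1.06 (adjusted p = 2.4e-06), and the lineage transcription factors Olig1 and Olig2 fell by 0.65 and 0.76 (adjusted p = 9.1e-05 and 4.2e-04). Cholesterol synthesis genes fell with them, 11 of 22 lower, 2 higher and 9 not called (14 over the list alone, median -0.47, adjusted p = 0.0031; adjusted p = 0.077 with an estimated correlation). Msmo1, a sterol demethylation enzyme, fell by 1.21 and Hmgcs1, the HMG-CoA synthase, by 0.88 (adjusted p = 7.4e-07 and 3.3e-06), while Fdft1, squalene synthase, rose by 0.71 (adjusted p = 8.3e-06).

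Neuronal lists fell as well. Striatal projection neuron genes had 21 of 35 lower, 6 higher and 8 not called (28 over the list alone, median -0.19, limma camera adjusted p = 1.9e-04, and 0.0247 with an estimated correlation). Bcl11b, the transcription factor that specifies these neurons, fell by 0.69 and Gnal, the G protein that couples their dopamine and adenosine receptors, by 0.53 (adjusted p = 1.2e-06 and 2.3e-06). Itpka, an inositol trisphosphate kinase of dendritic spines, rose by 0.83 (adjusted p = 2.8e-06). Cortical excitatory neuron genes had 11 of 16 lower, 0 higher and 5 not called (11 over the list alone, median -0.91, adjusted p = 1e-05, and 0.0233 with an estimated correlation). Slc17a7, the vesicular glutamate transporter of cortical neurons, fell from 17579.5 to 7644, Tbr1, a deep-layer transcription factor, from 2533 to 757 and Rorb, a layer 4 nuclear receptor, from 1314 to 610.2 (adjusted p = 8.0e-07, 2.2e-05 and 4.5e-05). The labels give no brain region, so lower expression in these neurons cannot be told apart from a different share of cortex in the tissue. Striatal interneuron genes had 4 of 14 lower, 0 higher and 10 not called (3 over the list alone, median -0.73, adjusted p = 0.0207; adjusted p = 0.112 with an estimated correlation). Parvalbumin, Pvalb, fell by 1.10 and the nitric oxide synthase Nos1 by 0.86 (adjusted p = 7.8e-05 and 0.00105). Glutamate and GABA receptor genes had 16 of 35 lower, 4 higher and 15 not called (20 over the list alone, median -0.34, adjusted p = 0.00181; adjusted p = 0.158 with an estimated correlation). The GABA-A subunits Gabra2 and Gabrb1 fell by 1.17 and 0.78 (adjusted p = 3.3e-05 and 3.1e-05), and Grin1, the obligatory NMDA receptor subunit, rose by 0.56 (adjusted p = 1.4e-05).

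Astrocyte genes split into a homeostatic part that was lower and a reactive part that was higher in HD. On the astrocyte list 15 of 25 genes fell, 4 rose and 6 were not called (19 over the list alone, median -0.32, limma camera adjusted p = 0.00123; adjusted p = 0.136 with an estimated correlation). Slc1a2, the main glutamate transporter, fell by 0.91 and Kcnj10, the potassium channel Kir4.1, by 0.79 (adjusted p = 4.5e-07 and 6.1e-07), while connexin 30, Gjb6, rose by 0.95 (adjusted p = 8.0e-07). The intermediate filament gene Gfap rose from 5584 ± 37.3 to 8075 ± 79.6 (log2 0.53, SE 0.06, adjusted p = 1.0e-04, chromosome 11, 102887336 to 102900912 in mm10). Among reactive astrocyte genes 12 of 30 rose, 0 fell and 18 were not called (12 over the list alone, median 0.67, adjusted p = 0.0031; adjusted p = 0.169 with an estimated correlation). Besides Lcn2, Fkbp5, a chaperone of the glucocorticoid receptor, rose by 1.61, Stat3, the transcription factor of reactive gliosis, by 1.11 and complement C4b went from 3933 to 9032 (adjusted p = 4.8e-08, 1.7e-06 and 5.5e-06).

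Vascular, blood and interferon genes were lower. Endothelial and mural genes had 9 of 20 lower, 1 higher and 10 not called (10 over the list alone, median -0.49, limma camera adjusted p = 0.0088; adjusted p = 0.0949 with an estimated correlation). Itm2a, a membrane protein of brain endothelium, fell by 1.47, Kdr, the VEGF receptor 2, by 1.46 and Rgs5, a pericyte G protein regulator, by 0.96 (adjusted p = 1.3e-05, 9.8e-05 and 4.4e-05). All 5 tested blood genes fell (5 over the list alone, median -1.60, adjusted p = 0.00233; adjusted p = 0.226 with an estimated correlation), among them the globins Hbb-bs by 1.79 and Hba-a1 by 1.24 (adjusted p = 1.6e-06 and 2.0e-05). Interferon response genes had 7 of 31 lower, 1 higher and 23 not called (7 over the list alone, median -0.70, adjusted p = 0.0419; adjusted p = 0.226 with an estimated correlation). The interferon call was lost without 1 of 5 libraries (adjusted p from 0.0561 to 0.112), with equal totals (0.0523), upper-quartile factors (0.0942), trimmed-mean factors (0.0563), an added constant of 1 (0.0577) and the stricter filter (0.156). The interferon-induced GTPase Gbp3 fell from 375 to 167 and Ifi44, an antiviral protein, by 2.28 (adjusted p = 0.00347 and 0.00994).

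Ribosomal protein and circadian clock genes rose and histone genes fell. Of 77 cytosolic ribosomal protein genes 70 were higher, 0 lower and 7 not called (72 over the list alone, median 0.44, limma camera adjusted p = 9.7e-19; adjusted p = 0.11 with an estimated correlation), for instance the small-subunit gene Rps27 by 0.88 and the large-subunit gene Rpl17 by 0.60 (adjusted p = 1.1e-06 and 1.6e-06). Clock genes had 10 of 16 higher, 2 lower and 4 not called (12 over the list alone, median 0.43, adjusted p = 0.00343; adjusted p = 0.0784 with an estimated correlation). The repressors Per1, Cry2 and Cry1 rose by 1.39, 1.10 and 0.85 (adjusted p = 6.1e-07, 1.3e-06 and 8.3e-06), and Dbp, a clock output factor, fell by 0.84 (adjusted p = 5.9e-06). Histone genes had 16 of 25 lower, 2 higher and 7 not called (18 over the list alone, median -1.38, adjusted p = 2.2e-04; adjusted p = 0.109 with an estimated correlation). Hist1h2bc, an H2B gene, fell by 1.68 and Hist2h3c1, an H3 gene, by 2.76 (adjusted p = 3.0e-06 and 2.0e-05). Among genes with a mean of at least 1000 the histone list was not called (median -0.38, adjusted p = 0.139). Most histone messages lack a poly(A) tail, and the libraries were made from poly(A) RNA.

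Camera called 16 of 35 lists in this comparison, 3 higher and 13 lower. The 4 that held with an estimated correlation are those of microglia, oligodendrocytes, cortical excitatory neurons and striatal projection neurons. Some lists lost their call although their estimate was below the preset 0.01. They were striatal interneurons (-0.0544), clock (-0.035), cholesterol synthesis (-0.0253) and endothelial and mural cells (-0.0218). A higher correlation in these lists did not end their calls. The rotation test fry, which asks for a shift against 0 and not against other genes, called 31 lists. Matrix metalloproteinases and inhibitors had 7 higher and 7 lower of 25, with 11 not called and 14 over the list alone (limma camera adjusted p = 0.522). Timp2, an inhibitor that also helps to activate pro-MMP2, rose by 1.16, the protease Adamts1 rose by 1.65 and Mmp17, a membrane-anchored metalloproteinase, fell by 1.29 (adjusted p = 3.0e-07, 1.8e-05 and 4.7e-06). Extracellular matrix genes had 4 higher and 9 lower of 34, with 21 not called and 13 over the list alone (adjusted p = 0.16). The proteoglycan gene Ncan fell by 1.30 and Sparc, a collagen-binding glycoprotein, rose by 0.74 (adjusted p = 2.8e-07 and 2.3e-05). Immediate early genes had 9 higher and 9 lower of 21, with 3 not called and 18 over the list alone (adjusted p = 0.527). The activity-driven Arc and Npas4 fell by 1.92 and 1.27 (adjusted p = 8.2e-07 and 3.4e-05). Complement and cytokine genes had 6 higher and 3 lower of 22, with 13 not called and 9 over the list alone (adjusted p = 0.527). The monocyte chemokine Ccl2 rose by 3.99 and the alarmin Il33 fell by 2.60 (adjusted p = 2.3e-05 and 6.9e-07).

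Members also changed on other uncalled lists, given here as higher, lower and tested, with the number called over the list alone in brackets. Oxidative phosphorylation had 11, 9 and 33 (21), heat shock and unfolded protein response 6, 7 and 25 (14), antigen presentation 3, 3 and 22 (5), fibroblast and meninges 1, 5 and 18 (5), ependymal cilium 4, 0 and 14 (3) and developmental transcription factors 3, 1 and 12 (4). Cell cycle had 3, 0 and 20 (2), clustered protocadherin beta 1, 2 and 22 (3), choroid plexus 1, 2 and 14 (2), thalamic and midbrain neurons 0, 2 and 9 (1) and lymphocytes 1, 1 and 9 (2). Ptgds, a prostaglandin synthase of meninges and oligodendrocytes, rose by 2.78 (limma adjusted p = 6.7e-09), and Hsph1, a cytosolic chaperone, fell by 1.16 (adjusted p = 4.2e-07). Slc17a6, the vesicular glutamate transporter of thalamic neurons, fell by 2.22 (adjusted p = 5.9e-05), and Kcne2, a potassium channel subunit of choroid plexus, rose by 2.57 (adjusted p = 0.00545). The ependymal histidine decarboxylase Hdc rose from 75.4 to 175, and H2-Eb1, an MHC class II chain, fell by 2.54 (adjusted p = 0.00518 and 4.1e-04). Median, mean and test differed in sign for 6 lists: canonical Wnt targets (median 0.07, mean -0.25, test lower), calcineurin and NFAT (-0.04, 0.04, lower), metalloproteinases (-0.26, 0.04, lower), immediate early genes (0.04, -0.12, lower), heat shock (-0.15, 0.00, lower) and protocadherin beta (0.05, 0.01, lower).

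Wnt5b, a ligand of non-canonical Wnt signalling, was at 74.6, 63.8 and 57.7 in the WT libraries and 63.8, 44.2 and 49.3 in the HD libraries (log2 -0.31, SE 0.73, limma adjusted p = 0.775). Mmp14, a membrane-bound metalloproteinase that cleaves matrix and pro-MMP2, was at 698 ± 19.8 and 770.1 ± 49.8 (0.14, SE 0.11, adjusted p = 0.338). Nfatc2, a calcium-regulated transcription factor, fell from 2609.5 ± 96.6 to 1774 ± 19.9 (-0.56, SE 0.19, adjusted p = 0.046). The call of Nfatc2 was lost without any single library of the 2 groups, with the WNT5B libraries kept in the fit (adjusted p from 0.0965 to 0.123). Its relatives Nfatc1, Nfatc3 and Nfatc4 were not called (log2 -0.05, 0.18 and -0.04, adjusted p = 0.951, 0.39 and 0.961). Wnt5a, the closest relative of Wnt5b, rose from 331 to 531 (0.68, adjusted p = 0.0199), a call lost in 5 of 6 omissions of a library. The gelatinase Mmp2 and Htt itself, the Huntington gene, were not called (log2 -0.26 and 0.12, adjusted p = 0.418 and 0.078). With a weight per group Mmp14, Mmp2, Nfatc3 and Htt were called as well (adjusted p = 0.0123, 0.0342, 4.9e-04 and 1.7e-06). The same genes were called with only the 6 libraries of the contrast (limma adjusted p = 0.0157, 0.0409, 1.0e-04 and 8.0e-07). Htt was also called with voom weights (0.0148) and with the length and GC trend removed (0.19, 0.0143). The N171-82Q transgene is a human sequence, and the mouse Htt value need not include it. In mm10 Wnt5b lies at chromosome 6, 119432531 to 119544347, Mmp14 at chromosome 14, 54431612 to 54445364 and Nfatc2 at chromosome 2, 168476410 to 168601657.

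On the non-canonical Wnt list 8 genes rose, 9 fell and 18 were not called of 35 (17 over the list alone, median -0.03, limma camera adjusted p = 0.581). Wnt7b, a ligand of brain vessel growth, fell by 0.97, the receptor Fzd2 by 1.24 and the ligand Wnt4 by 1.49 (adjusted p = 4.1e-05, 1.1e-04 and 1.4e-04). Canonical Wnt targets had 1 higher, 5 lower and 15 not called of 21 (6 over the list alone, adjusted p = 0.477). The cell cycle driver Ccnd1 fell by 1.93 and Tcf7, a partner of beta-catenin, by 1.30 (adjusted p = 1.2e-04 and 2.1e-04). For calcineurin and NFAT 9 rose, 10 fell and 13 were not called of 32 (19 over the list alone, adjusted p = 0.862). The kinase Camk2a fell by 0.43, and Ppp3r1, the regulatory subunit of calcineurin, rose by 0.51 (adjusted p = 5.5e-06 and 2.9e-06).

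**Figure D2:**
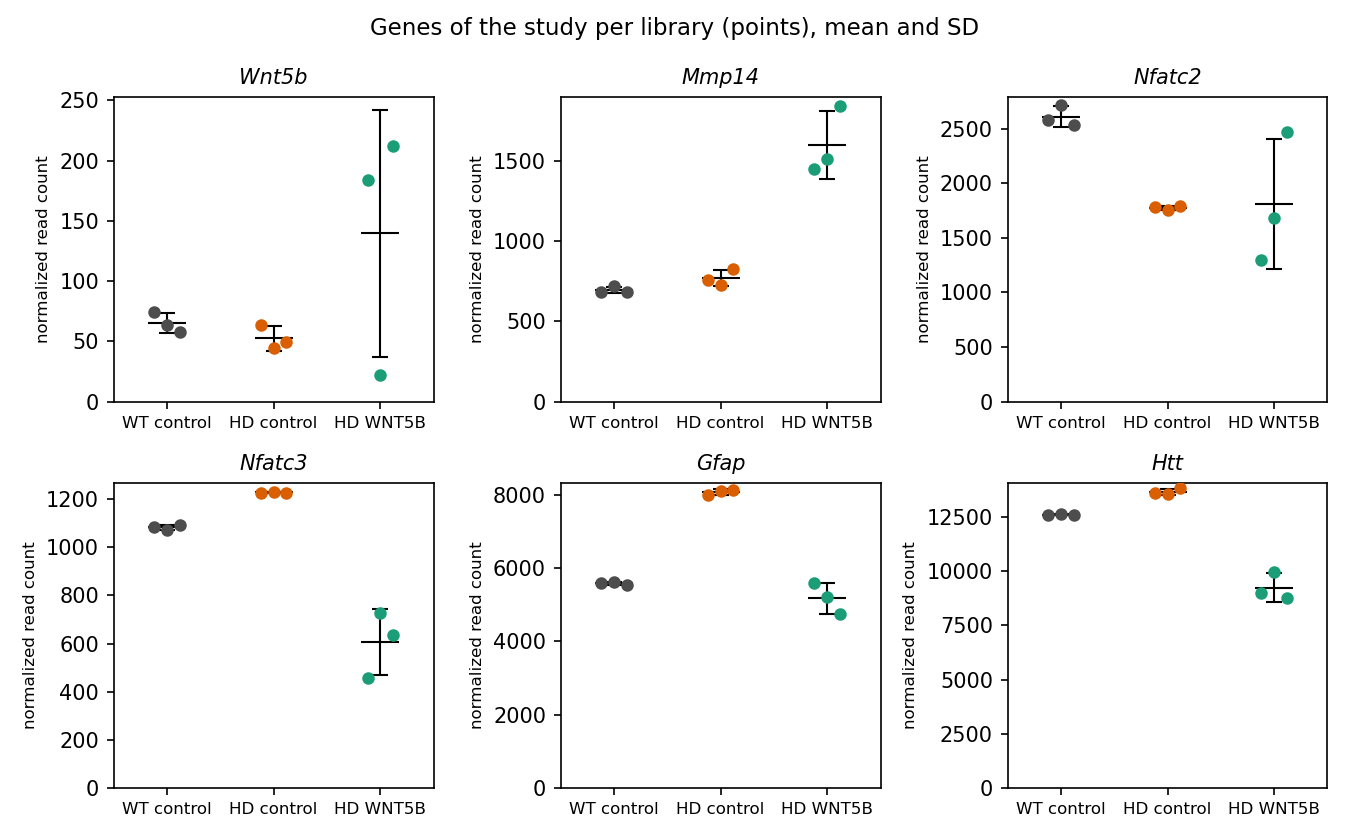
Normalized read counts of Wnt5b, Mmp14, Nfatc2, Nfatc3, Gfap and Htt in WT control, HD control and HD WNT5B libraries. Points are libraries (n = 3 per group), with group mean and SD.

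In HD mice given the WNT5B virus, Mmp14 was at 1602 ± 212 against 770.1 ± 49.8 in HD mice given the control virus (n = 3 libraries each), a rise of 1.05 in log2 (SE 0.11, limma adjusted p = 2.3e-05). With equal library totals that rise was 0.50 (limma adjusted p = 0.0038). The median absolute log2 change over all genes tested was 1.1862, so a change of this size was common in this comparison. Oxidative phosphorylation and ribosomal protein genes were higher as groups, and clustered protocadherin beta and extracellular matrix genes were lower, each with adjusted p = 0.175 with an estimated correlation, and the 2 lower lists also lost their call with the length and GC trend removed. Gfap fell from 8075 ± 79.6 to 5176 ± 418 (log2 -0.64, SE 0.06, adjusted p = 6.3e-06), and the change was -1.199 with equal totals and -1.029 with the length and GC trend removed. Of 15411 genes 11942 changed at Benjamini-Hochberg adjusted p < 0.05, 5516 higher and 6426 lower, and 8077 changed at least 2-fold (3635 higher, 4442 lower). With a weight per group 10797 passed, 10579 of them shared, and scaled to equal totals 32.17 percent of the changed genes were higher instead of 46.19.

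The libraries labelled WNT5B differ from the other 6 as a whole, which bears on every gene below. They hold 14291 to 14588 genes above 0 against 17027 to 17349, and 194 to 324 genes at 1 to 10 reads against 1778 to 1952. The 10 highest genes take 6.217 to 6.753 percent of the signal against 3.018 to 3.107. Short transcripts were higher and long ones lower: among 8641 genes with a mean of at least 1000, the median log2 change ran from 1.85 in the shortest eighth (383 to 1813 nt) to -1.09 in the longest (7095 to 123179 nt), while HD against WT ran from 0.13 to 0.03. Spearman correlation with transcript length was -0.483 (HD against WT -0.079) and with GC content 0.296 (HD against WT -0.019). With the length and GC trend of each library removed 11439 genes were called, and 10298 of the 11942 called at first were among them, 9752 in the same direction and 546 in the opposite one. The median absolute log2 change of the 11942 went from 1.429 to 1.166. Of 152 named changes called at first, 48 moved by more than 1.5 times and 4 changed sign with the trend removed, and 27 and 0 with equal totals. Of 35 list medians 18 moved by more than 1.5 times and 4 changed sign with the trend removed, and 23 and 4 with equal totals. Chosen after the values were seen, the reference gene Actb, a cytoskeletal actin, had means of 64505, 91503 and 434315 in WT, HD and WNT5B libraries, Gapdh, a glycolytic enzyme, 61385, 71612 and 16564, and the choroid plexus carrier Ttr 693, 679 and 12656.

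**Figure D3:**
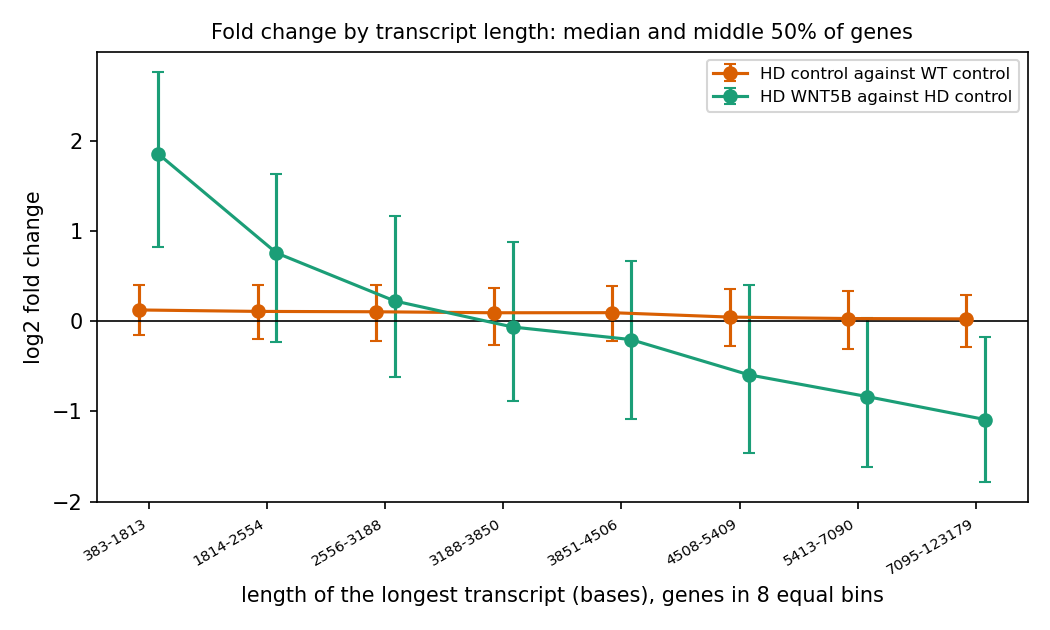
Log2 fold change by eighth of transcript length for HD control against WT control and for HD WNT5B against HD control. Points are medians and bars span the middle 50 percent of the genes (8641 genes with a mean of at least 1000).

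Wnt5b itself was at 184, 22.5 and 212 in the 3 libraries labelled WNT5B, against 44.2 to 63.8 in HD controls (log2 0.88, SE 0.73, limma adjusted p = 0.298). Without replicate 2 the change was 1.87 (adjusted p = 1.1e-04), with equal totals 0.36 and with the length and GC trend removed 0.19. Replicate 2 lay below every HD control, so mouse Wnt5b does not bear out its label. The species and coding sequence of the transgene are not given, and reads from it need not count as mouse Wnt5b. Nfatc2 was not called at the deposited scale (1774 ± 19.9 and 1812 ± 596, log2 -0.02, adjusted p = 0.929), and was lower with equal totals (-0.57, adjusted p = 0.0267) and without WNT5B replicate 3 (-0.27, 0.0411). Nfatc3, a NFAT factor of brain and immune cells, fell from 1228 to 606 ± 137 (-1.04, adjusted p = 2.5e-04), and with the length and GC trend removed the change was -0.24 (adjusted p = 0.228), against -1.595 with equal totals. Nfatc1, Nfatc4, Wnt5a and Mmp2 were not called (-0.99, 0.36, -0.35 and 0.24, adjusted p = 0.0924, 0.526, 0.13 and 0.36). With equal totals Nfatc1 and Wnt5a were called lower (-1.54 and -0.90, adjusted p = 0.018 and 0.003). Nfatc1 was also called with a weight per group (0.0457), with voom (0.0201) and without WNT5B replicate 2 or 3 (0.0217 and 0.0343). Wnt5a was also called with voom (0.0475) and without replicate 3 (0.00135), and Mmp2 was called higher without replicate 1 (0.44, adjusted p = 0.0236). The direction of Wnt5a in the WNT5B libraries depends on the setting: against WT it was called higher with the length and GC trend removed (1.21, limma adjusted p = 9.9e-04). Htt fell from 13666 to 9241 (-0.57, adjusted p = 5.4e-06), and the change was 0.08 with the trend removed and -1.12 with equal totals.

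The 6 largest rises that met the naming rule were Gdf1, Gp1bb, Atp5e, Jsrp1, Ndufa2 and Atp5k, and 3 of them encode parts of the respiratory chain or ATP synthase. Atp5e, the epsilon subunit of ATP synthase, went from 1398 ± 67.6 to 122512 ± 7884 (log2 6.45, SE 0.06, limma adjusted p = 2.0e-11). Ndufa2, a complex I subunit, went from 2106 to 152439 (6.17, adjusted p = 2.0e-11; 4.06 with the length and GC trend removed, 11.54 percent of exon bases shared) and Atp5k, another ATP synthase subunit, from 2606 to 133945 (5.68, adjusted p = 6.5e-11; 3.30 with the trend removed). Jsrp1, a protein of the muscle junctional membrane, rose from 91.8 to 7115 (6.23, adjusted p = 2.8e-10). Gp1bb, a platelet adhesion receptor chain, rose from 193 to 50738 (8.12, adjusted p = 1.9e-07), with 91.14 percent of its exon bases shared with Sept5. The growth factor gene Gdf1 rose from 119.7 to 18728 (8.26, adjusted p = 1.3e-04), all of its exon bases lie within Cers1, and with a weight per group its call was lost (adjusted p = 0.0784). In mm10 Atp5e lies at chromosome 2, 174461072 to 174464105, Ndufa2 at chromosome 18, 36742332 to 36744557 and Gp1bb at chromosome 16, 18620317 to 18622403.

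The 6 largest falls were gene models that share exons with a neighbour, except for Pstpip2. Sept2, a septin of the cytoskeleton whose exon bases are all shared with a second gene model of that name, had a mean of 3783 in HD controls and less than the value of 1 read in the WNT5B libraries (limma adjusted p = 4.6e-11). The same held for a second model of Myl12b, a myosin light chain (ENSMUSG00000117098.1, 61.53 percent shared, mean 3232 in HD controls, adjusted p = 1.4e-10), and a second model of Zc3h11a, a zinc finger protein of mRNA export (ENSMUSG00000102976.6, 72.87 percent shared, mean 1164, adjusted p = 1.0e-07). 1 of 2 models of Fam220a, a regulator of STAT3 dephosphorylation (ENSMUSG00000083012.9), fell from 721 to 2.28 (log2 -7.07, adjusted p = 9.3e-07, 61.03 percent shared), and Moap1, a BAX partner in apoptosis, from 724 to 7.36 (-6.90, adjusted p = 2.8e-05, 87.73 percent shared). With voom weights on recovered reads the Fam220a model and the Zc3h11a model were not called (limma adjusted p = 0.0532 and 0.0837). Pstpip2, an actin regulator of macrophages, fell from 895 ± 12.7 to 32.2 ± 55.8 (-6.54, adjusted p = 8.9e-04, chromosome 18, 77789914 to 77882879 in mm10). Of 6 genes above 500 in both control groups and under 3 with WNT5B, 5 overlap another gene (83.33 percent, against 8.19 percent of all tested genes).

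Camera called 4 of 35 lists for WNT5B against HD control, and 0 with an estimated correlation. The estimate was below the preset 0.01 for protocadherin beta (7e-04) and extracellular matrix (-0.0224). A higher correlation in these lists therefore did not end their calls. Of 33 oxidative phosphorylation genes 32 rose and 1 fell (33 over the list alone, median 2.78, limma camera adjusted p = 3e-14; adjusted p = 0.175 with an estimated correlation), for instance Atp5j2, an ATP synthase subunit, from 3031 to 96783 and Ndufb7, a complex I subunit, from 2730.2 to 65612 (adjusted p = 2.0e-11 and 2.0e-11). Among 77 ribosomal protein genes 74 rose, 1 fell and 2 were not called (75 over the list alone, median 2.69, adjusted p = 2e-22; adjusted p = 0.175 with an estimated correlation), and Rpl36 and Rpl32, both of the large subunit, rose by 5.47 and 3.71 (adjusted p = 2.0e-11 and 2.0e-11). With the length and GC trend removed the 2 medians were 1.74 and 1.41 and both lists kept their call, while Rpl36 and Rpl32 rose by 2.40 and 2.20. The removal used the longest annotated transcript, so genes read mostly from a shorter one may be corrected too little. The kept calls therefore do not exclude a length effect. For clustered protocadherin beta 19 of 22 fell, 1 rose and 2 were not called (20 over the list alone, median -1.77, adjusted p = 0.0139; adjusted p = 0.175 with an estimated correlation). The neuronal adhesion genes Pcdhb20 and Pcdhb17 fell by 1.57 and 1.61 (adjusted p = 3.9e-07 and 2.0e-06; Pcdhb17 by 0.95 with the trend removed), and with the trend removed the list had a median of -1.08 and no call (adjusted p = 0.105). On the extracellular matrix list 22 of 34 fell, 3 rose and 9 were not called (25 over the list alone, median -0.88, adjusted p = 0.0477; adjusted p = 0.175 with an estimated correlation). Its call was lost with a weight per group (0.0538), with the trend removed (0.177), with no filter (0.0601), with overlapping genes left out (0.0651), at a mean of at least 1000 (0.187), with an added constant of 1 (0.0541) and without HD control replicate 3 or WNT5B replicate 1 (0.0516 and 0.0739). Sparcl1, an astrocyte protein that promotes synapses, fell by 1.25 and Col4a2, a collagen of the vascular basement membrane, by 1.46 (adjusted p = 4.1e-08 and 4.4e-07). The test fry called 33 lists.

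**Figure D4:**
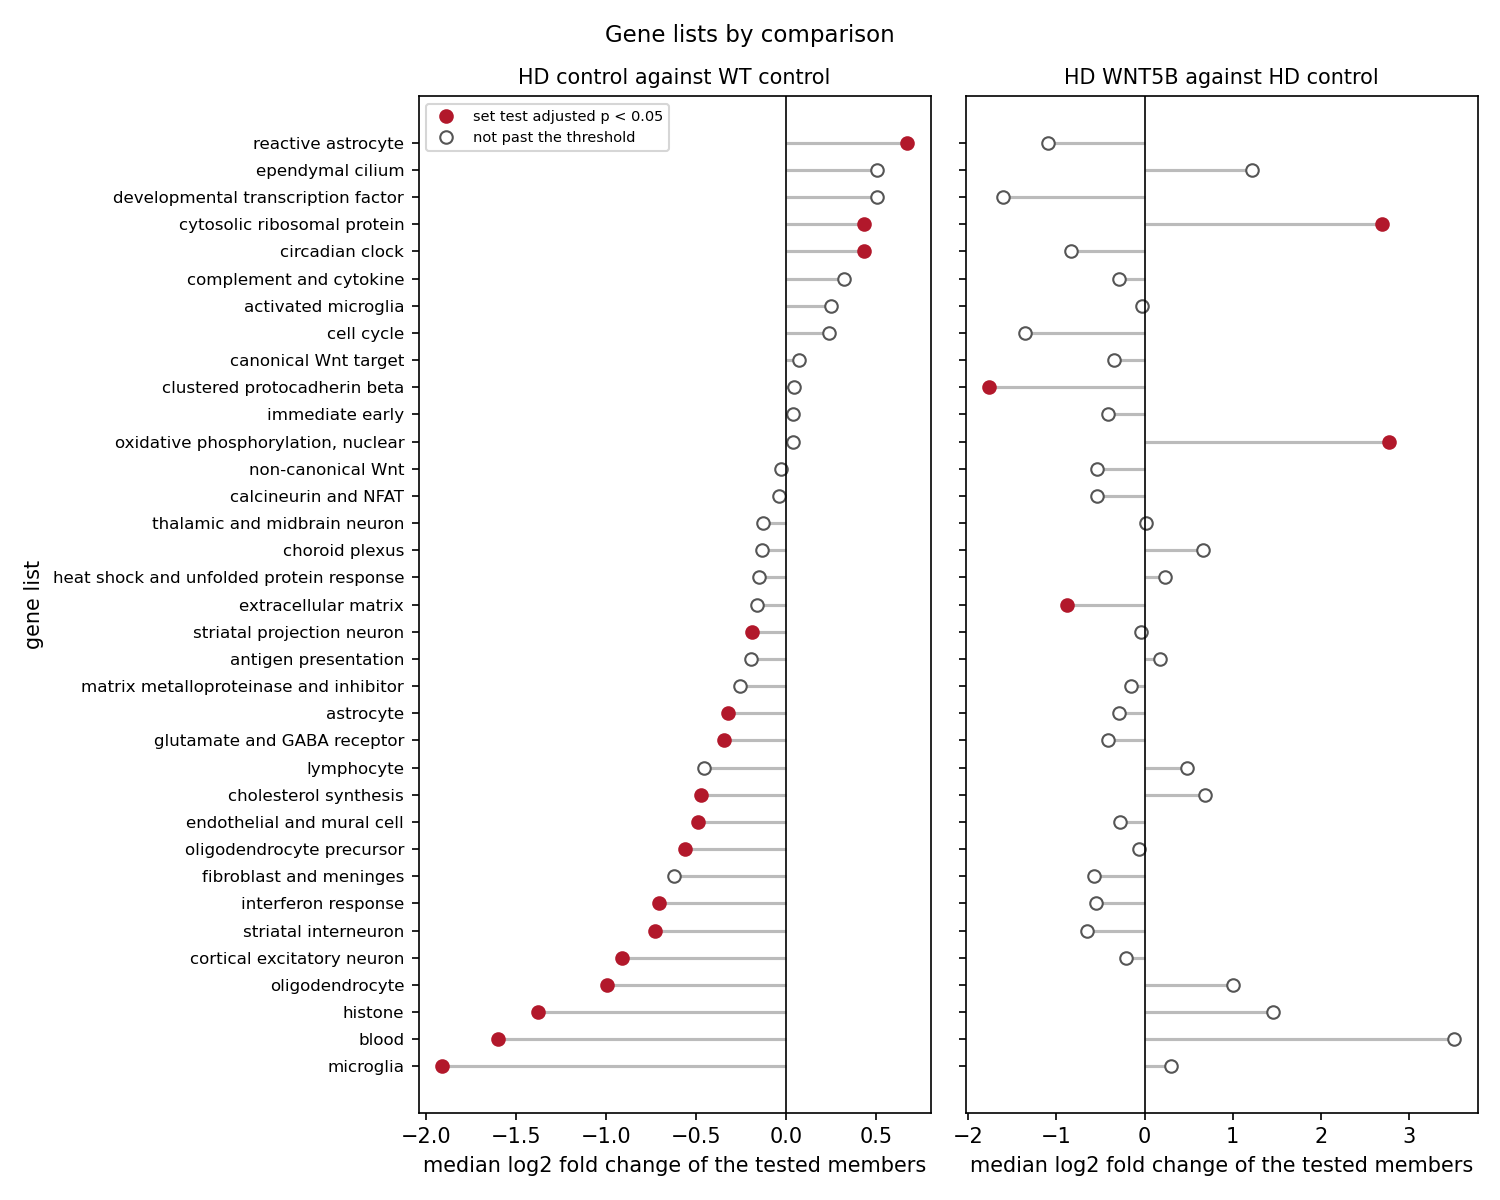
Median log2 fold change of the 35 tested gene lists for HD control against WT control and for HD WNT5B against HD control (n = 3 libraries per group). Filled points mark lists with a camera adjusted p under 0.05.

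On the lists of the pathway the series is about, members went both ways. Non-canonical Wnt genes had 10 higher, 16 lower and 9 not called of 35 (26 over the list alone, median -0.54, limma camera adjusted p = 0.678; median -1.095 with equal totals and -0.03 with the length and GC trend removed). The kinase Nlk rose by 1.96, the formin Daam2 fell by 1.92 and Ror1, a receptor for WNT5 ligands, fell by 2.84 (adjusted p = 1.1e-08, 2.9e-08 and 2.2e-07). Calcineurin and NFAT genes had 8 higher, 17 lower and 7 not called of 32 (25 over the list alone, median -0.54, adjusted p = 0.294; median -1.09, adjusted p = 0.0482 with equal totals and -0.24 with the trend removed). Camk2a fell by 2.11, Ppp3r1 fell by 1.55 and Itpr2, the inositol trisphosphate receptor of astrocytes, rose by 2.01 (adjusted p = 6.0e-11, 3.0e-10 and 4.8e-08). Metalloproteinases and inhibitors had 9 higher, 9 lower and 7 not called of 25 (18 over the list alone, median -0.16, adjusted p = 0.974; median -0.71 with equal totals). Mmp15, a membrane-bound relative of Mmp14, rose by 2.45, Bsg, an inducer of metalloproteinases, rose by 2.15 (0.98 with the length and GC trend removed), and the inhibitor Timp3 fell from 10342 to 2343 (adjusted p = 7.9e-08, 7.9e-10 and 2.6e-09). Canonical Wnt targets had 5 higher, 8 lower and 8 not called of 21 (13 over the list alone, adjusted p = 0.745), and Axin2, a feedback inhibitor of beta-catenin, fell by 1.72 (adjusted p = 9.1e-07).

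Cell type lists were not called with WNT5B, and their members parted. Microglia genes had 9 higher, 2 lower and 9 not called of 20 (10 over the list alone, median 0.30, limma camera adjusted p = 0.129), and the median was -0.23 with equal totals. Cx3cr1 went from 588 to 19939.8 ± 1666 (log2 5.07, adjusted p = 5.2e-11), above its WT mean of 4765, and the microglial calcium-binding protein gene Aif1 rose by 4.67 (adjusted p = 1.1e-08). Oligodendrocyte genes had 12 higher, 6 lower and 2 not called of 20 (18 over the list alone, median 0.999, adjusted p = 0.129; median 0.44 with equal totals and 0.60 with the length and GC trend removed). Mal, a myelin lipid raft protein, rose by 1.79, while Mobp, a basic protein of compact myelin, fell by 1.18 (adjusted p = 8.3e-11 and 2.2e-09). Striatal projection neuron genes had 11 higher, 14 lower and 10 not called of 35 (25 over the list alone, adjusted p = 0.974). The homeobox gene Dlx6 rose by 4.40 and Rgs9, a brake on dopamine receptor signals, by 1.83, and Gnal fell by 2.16 (adjusted p = 2.5e-11, 9.0e-11 and 6.0e-11). Astrocyte genes had 8 higher, 13 lower and 4 not called of 25 (21 over the list alone, adjusted p = 0.745). The calcium-binding S100b rose by 3.99 and Gjb6 by 1.85, and Slc1a2 fell by 1.72 (-0.69 with the length and GC trend removed; adjusted p = 2.0e-10, 7.1e-10 and 3.2e-10). Reactive astrocyte genes had 8 higher, 13 lower and 9 not called of 30 (21 over the list alone, adjusted p = 0.873). Stat3 fell by 1.95 (adjusted p = 4.0e-09), and the interferon-induced GTPase Gbp2 was listed at 0 in all 3 WNT5B libraries.

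Other lists are given as higher, lower and tested, with the number called over the list alone in brackets. Striatal interneurons had 4, 6 and 14 (10), cortical excitatory neurons 6, 5 and 16 (11), thalamic and midbrain neurons 3, 3 and 9 (6), oligodendrocyte precursors 6, 6 and 15 (12), endothelial and mural cells 7, 8 and 20 (15), choroid plexus 5, 2 and 14 (7) and ependymal cilium 10, 2 and 14 (12). Activated microglia had 7, 6 and 20 (12), interferon response 5, 8 and 31 (10), antigen presentation 8, 6 and 22 (14), lymphocytes 3, 3 and 9 (6), complement and cytokines 7, 7 and 22 (14) and fibroblast and meninges 4, 3 and 18 (6). Glutamate and GABA receptors had 15, 17 and 35 (33), immediate early genes 5, 11 and 21 (16), cholesterol synthesis 13, 9 and 22 (22), heat shock 12, 8 and 25 (20), clock 4, 12 and 16 (16), cell cycle 3, 8 and 20 (10) and developmental transcription factors 1, 5 and 12 (6). Blood had 4, 0 and 5 (4) and histones 15, 4 and 25 (18), each with a limma camera adjusted p of 0.0826, and of 0.0268 with equal totals. With only the 6 libraries of the contrast the histone list was called (0.0132). Nos1 fell by 3.28, Lamp5, a synaptic vesicle protein of forebrain neurons, rose by 1.43 (0.87 with equal totals), Cldn5, the tight junction protein of brain endothelium, rose by 4.10 (2.73 with the length and GC trend removed) and Rgs5 fell by 1.93 (-1.235 with the trend removed) (adjusted p = 5.4e-08, 3.8e-09, 1.2e-10 and 7.9e-08). Gabrd, a GABA-A subunit outside synapses, and Gabra2 rose by 2.71 and 3.63, the activity-driven Fos fell by 2.91, and Hsp90aa1, an inducible chaperone, rose by 3.88 (adjusted p = 9.1e-11, 3.8e-09, 2.1e-07 and 5.8e-09). Usp2, a deubiquitinase of the clock, rose by 2.29, Nr1d2, a clock repressor, fell by 1.37 (-0.60 with the length and GC trend removed), and the axonemal protein gene Hydin was listed at 0 in the WNT5B libraries (adjusted p = 2.3e-10 and 5.8e-09 for the first 2). Median, mean and test differed in sign for striatal projection neurons (-0.04, 0.04, lower), cortical excitatory neurons (-0.21, -0.08, higher), thalamic and midbrain neurons (0.01, -0.46, higher), astrocytes (-0.29, 0.04, lower), activated microglia (-0.03, 0.05, higher), complement and cytokines (-0.29, -0.64, higher) and fibroblast and meninges (-0.57, -0.32, higher).

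Genes that differed between HD and WT were called in the opposite direction with WNT5B for 3342 of 6957 (48.0 percent) and in the same direction for 2695 (38.7 percent). Independent lists of these sizes give 2713 (39.0 percent) and 2678 (38.5 percent). Lower-then-higher genes numbered 1624 against 1139.3 for independent lists, and higher-then-lower genes 1718 against 1573.7. Higher-then-higher genes numbered 1625 against 1350.8 and lower-then-lower genes 1070 against 1327.2, so genes higher in HD exceeded independent lists in both directions and only genes lower in HD did so in the opposite direction alone. Cx3cr1 and Slc17a7 went down in HD and up with WNT5B (Slc17a7 by 0.99, limma adjusted p = 1.4e-07; 0.43 with equal totals and 0.66 with the length and GC trend removed), and Gfap and Stat3 went up in HD and down with WNT5B. Slc1a2 and Gnal went down in both steps, and Nfkbia, the inhibitor of NF-kappaB, went up in both (1.59 and 1.67, adjusted p = 8.7e-07 and 3.5e-08; the second 0.79 with the trend removed). The 2 comparisons share the HD control libraries with opposite sign, which alone gives a negative correlation. The covariance across genes was -0.182, against -0.00643 (-0.00889 to -0.00428) in 100 simulations of unchanged groups. With the HD controls split 1 against 2 so that no library is in both changes, chosen after the values were seen, it was -0.18 to -0.17 over 6 splits. The correlation was -0.129 and the simulated mean -0.103, which are not on the same scale because simulated changes hold only noise.

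Compared with WT, HD mice given WNT5B had higher oxidative phosphorylation and ribosomal protein genes and lower extracellular matrix and protocadherin beta genes (n = 3 libraries each), all 4 with adjusted p = 0.146 to 0.147 with an estimated correlation. Mmp14 was at 1602 ± 212 against 698 ± 19.8 (log2 1.19, SE 0.11, limma adjusted p = 9.9e-06), and with equal totals the rise was 0.61 (adjusted p = 0.00111). The median absolute log2 change over all genes tested was 1.217 at the deposited scale. Gfap was not called at the deposited scale (-0.11, adjusted p = 0.0911) and was lower with equal totals (-0.69, adjusted p = 1.7e-06), with the length and GC trend removed (-0.51, 2.4e-04), with upper-quartile factors (-0.24, 0.00221), with trimmed-mean factors (-0.145, 0.0408) and without WNT5B replicate 1 (-0.17, 0.0056). Wnt5b was not called (0.57, SE 0.73, adjusted p = 0.494) except without WNT5B replicate 2 (1.56, 3.0e-04), and its change was 0.02 with equal totals and -0.12 with the trend removed. Wnt5a was not called (0.33, limma adjusted p = 0.146), but was called higher with the trend removed (1.21, 9.9e-04) and without WNT5B replicate 2 (0.465, 0.0401). Nfatc2, Nfatc3 and Htt were lower (-0.58, -0.86 and -0.45, adjusted p = 0.0234, 8.2e-04 and 2.5e-05), and by more with equal totals (-1.16, -1.44 and -1.03, adjusted p = 6.2e-04, 2.2e-05 and 1.8e-08). With the trend removed Nfatc2 and Nfatc3 lost their calls (-0.25 and -0.05, adjusted p = 0.297 and 0.817) and Htt was called higher (0.27, adjusted p = 0.00112). The Nfatc2 call was also lost with only the 6 libraries (0.0558) and without WT replicate 1 or 2 or WNT5B replicate 2 (0.0532, 0.0661 and 0.0611). Of 15411 genes 12012 changed at Benjamini-Hochberg adjusted p < 0.05, 5526 higher and 6486 lower, and 8217 changed at least 2-fold (3687 higher, 4530 lower). With a weight per group 10960 passed, 10752 of them shared, and with equal totals 31.79 percent of the changed genes were higher instead of 46.0. This comparison shares libraries with the 2 others and carries the same length trend (Spearman -0.498).

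The largest rises against WT were Gp1bb (8.38), Ccl17, Nrtn, Gdf1 (6.51, not called with a weight per group, limma adjusted p = 0.16), Ndufa2 (6.33, and 4.07 with the length and GC trend removed) and Gnmt. Ccl17, a chemokine for T helper cells, went from 15.8 in WT to 329 in HD and 3080.4 ± 491 with WNT5B (7.34, adjusted p = 1.5e-09, chromosome 8, 94810453 to 94812036 in mm10). Nrtn, a growth factor of the GDNF family, rose by 6.74 and Gnmt, a methyltransferase of glycine, by 5.91 (adjusted p = 7.0e-08 and 3.9e-07). The largest falls were Sept2 and the second models of Myl12b and Zc3h11a, all under the value of 1 read with WNT5B, then the same Fam220a model (-7.60), Moap1 (-6.40) and Pcdhga12, a clustered protocadherin with 31.8 percent of exon bases shared (-6.23; adjusted p = 5.7e-07, 4.6e-05 and 0.00122). Of the 6957 genes called in HD, 3846 (55.28 percent) differed from WT in the same direction with WNT5B, against 2693 (38.7 percent) for independent lists. Both comparisons use the same 3 WT libraries, which alone favours the same direction. The covariance of the 2 changes was 0.434, against 0.00679 (0.00426 to 0.00948) in 100 simulations of unchanged groups, and 0.417 to 0.441 over 6 splits of the WT libraries 1 against 2. It is no separate result: the WNT5B change against WT is the sum of the 2 other changes. Its covariance with the HD change is therefore the variance of the HD change (0.616) plus the covariance of -0.182 given above. Any difference between HD and WT that is not wholly moved back exceeds a simulation of unchanged groups. The simulation and the splits therefore do not test how far WNT5B left genes on the HD side. Among the 1573 that changed at least 2-fold in HD, 919 were called on the same side of WT, 336 on the opposite side and 318 were not called.

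Against WT camera called the same 4 lists, and 0 with an estimated correlation. With the length and GC trend removed it also called striatal projection neurons (median -0.54, camera adjusted p = 0.0235) and striatal interneurons (-1.60, 0.0344). With equal totals it also called ependymal cilium (0.80, 0.0342). Oxidative phosphorylation had 32 of 33 higher and 1 lower (33 over the list alone, median 2.96, limma camera adjusted p = 4.9e-14; adjusted p = 0.146 with an estimated correlation), with Ndufb7 up by 4.82 and Atp5j2 by 4.65 (adjusted p = 1.2e-11 and 1.2e-11). Ribosomal protein genes had 75 of 77 higher and 1 lower (76 over the list alone, median 3.17, adjusted p = 2.2e-24; adjusted p = 0.147 with an estimated correlation), with Rpl36 up by 5.86 and Rps27 by 5.09 (adjusted p = 9.5e-12 and 1.0e-11). With the length and GC trend removed these 2 medians were 1.63 and 1.78 and both lists kept their call, and Rpl36 and Rps27 were up by 2.63 and 2.84. Ndufb7 and Atp5j2 moved little (4.90 and 4.32). Because the longest annotated transcript was used, the kept calls do not exclude a length effect. Extracellular matrix genes had 25 of 34 lower, 3 higher and 6 not called (28 over the list alone, median -1.37, adjusted p = 0.0109; adjusted p = 0.146 with an estimated correlation). Ncan fell by 1.46 and Tnr, the tenascin of perineuronal nets, by 1.76 (-0.80 with the trend removed), and Sparc rose from 12992 to 29955 (0.62 with equal totals; adjusted p = 3.1e-09, 1.6e-08 and 1.5e-07). Protocadherin beta genes had 17 of 22 lower, 0 higher and 5 not called (17 over the list alone, median -1.85, adjusted p = 0.0112; adjusted p = 0.146 with an estimated correlation), among them Pcdhb20 at -1.61 (adjusted p = 3.2e-07), and this list lost its call with the trend removed (median -1.2, adjusted p = 0.0716). On the microglia list 13 of 20 were below WT, 11 of them also below it in HD controls, and 6 were above (20 over the list alone, adjusted p = 0.554), and on the oligodendrocyte list 9 were below and 8 above of 20 (17 over the list alone, adjusted p = 0.891). Median, mean and test differed in sign for antigen presentation (-0.12, -0.49, higher), lymphocytes (0.26, 0.07, lower), metalloproteinases (-0.01, -0.15, higher), cholesterol synthesis (0.11, -0.12, higher) and histones (0.11, -0.17, higher).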

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

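The choices of scale, filter, test, replicate block, omission of haemoglobin and sex-linked genes and omission of single libraries were listed before the values were known. The added constants 1 and 30, trimmed-mean factors, equal totals, a weight per group, the length and GC trend, a mean of at least 1000 and omission of overlapping genes were chosen after seeing the data. A count-model test was not run, since whole reads could not be claimed. In HD against WT the count of 6957 genes went to 1573 at 2-fold or more, 12779 with a weight per group and 12858 with only the 6 libraries of the contrast, because the scatter of the WNT5B libraries then no longer enters the shared spread. For WNT5B against HD and against WT the counts of 11942 and 12012 went to 7797 and 7759 among genes with a mean of at least 1000, where 8641 genes were tested. With a replicate block the 3 counts were 6402, 11782 and 11891, and deviations of equal replicate numbers had correlations of -0.0225 to 0.0238. Genes called in HD and opposite with WNT5B were 48.0 percent, 39.995 with a weight per group (independent lists 39.0 and 35.2). The correlation across genes was -0.0978 with at least 1 CPM in 3 libraries and a mean of 50, -0.1583 with the length and GC trend removed and -0.1029 at a mean of at least 1000, against -0.1288. Leaving out 1 library of the groups compared gave 5421 to 5511, 11063 to 12532 and 11210 to 12621 genes, and 1 of the third group 8680 to 8949, 11509 to 11519 and 11614 to 11626. Over all 9 omissions there were 46.011 to 48.508 percent opposite (46.011, 46.161 and 46.172 without HD control replicates 1, 2 and 3) and correlations of -0.1403 to -0.1086. The call of Nfatc2 in HD against WT was lost without any 1 of the 6 libraries. Without WNT5B replicate 2 Wnt5b was called with WNT5B at 1.873, and without WNT5B replicate 1 or HD control replicate 3 the extracellular matrix list was not (limma camera adjusted p = 0.0739 and 0.0516). With the length and GC trend removed, Htt (0.081), Sst (-0.968), C1qb (-0.279) and B2m (-0.136) changed sign in WNT5B against HD. Among the lists it called, the test fry gave the direction opposite to camera for fibroblast and meninges in HD against WT (median -0.621). In WNT5B against HD it did so for striatal projection neurons (-0.036), astrocytes (-0.295), lymphocytes (0.484), endothelial and mural cells (-0.283) and glutamate and GABA receptors (-0.418). The interferon list in HD against WT was not called without any 1 WT library or without HD control replicate 2 or 3 (limma camera adjusted p = 0.0561 to 0.112). For other changes with a setting the cause was not tested. Over all settings and named genes, 81 values of HD against WT were weaker and 27 stronger, and 13 and 12 of WNT5B against HD.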

Other observations

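Some genes known from neutrophils were higher in HD than in WT libraries, and of the risen genes given here only Mmp9 is on a fixed list, that of metalloproteinases. They were picked after the values were seen and because they had risen, and no list of such genes was tested. S100a8 and S100a9, the calprotectin pair, rose from 2.01 and 3.28 to 274 and 318 (limma adjusted p = 6.6e-07 and 1.7e-06), Ngp, a granule protein, was listed at 0 in WT and had a mean of 188 in HD, and Mmp9, a gelatinase of neutrophils, rose from 30.8 to 202 (adjusted p = 3.4e-05). Selp, the P-selectin of endothelium, was listed at 0 in WT and WNT5B libraries and had a mean of 41.9 in HD. Socs3, the feedback inhibitor of STAT3, had means of 82.4, 831 and 89.9 in WT, HD and WNT5B libraries (adjusted p = 1.0e-04 for HD against WT and 2.3e-05 for WNT5B against HD). Haemoglobin genes were lower in HD, the opposite direction to these genes. Regrouping libraries, a test chosen after the results were seen, cannot test the counts: for each comparison the 6 libraries allow 10 splits, too few for a share under 0.05. Including the real 1, 1 of 10 splits called as many genes (6957, 11942 and 12012), and the highest other count was 0.

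The libraries labelled WNT5B stand apart from the other 6, and the 3 tests of this pattern were chosen only after the results were seen. Transcript length and GC content could make short genes such as Rpl36 and Ndufa2 higher. With the trend removed 11439 genes were called. Of the 11942 called at first, 9752 (81.66 percent) kept call and direction, 546 were called in the opposite direction and 1644 were not called. The tested form of this explanation thus did not account for most calls, though sizes shrank (median 1.429 to 1.166). The removal used the longest annotated transcript, so the kept calls do not exclude a length effect. Scatter from low library complexity could place genes on either side by chance, yet the WNT5B and HD libraries were fully separate in 90.29 percent of 8641 genes with a mean of at least 1000, where chance gives 10 percent. The HD and WT libraries were separate in 89.23 percent of the same genes, so such separation is not particular to the WNT5B libraries. The test covers only these well-filled genes and says nothing about lower ones. In the third test 0 groups had libraries on both sides of a value of 1 per read, but that value is a scaling factor and does not name a batch. A different library batch or preparation cannot be told apart from WNT5B, because every library that stands apart carries the WNT5B label. An HD library with the control virus made in the same batch as a WNT5B library would separate them.

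Glucocorticoid-responsive genes were higher in HD, seen first in Fkbp5, Sgk1, Tsc22d3 and Plin4. The 2 tests of this pattern were written after the first results were seen. The glucocorticoid test was written before the values of its genes were looked at. The genes of the time-of-day test belong to the circadian clock list, already tested here with 10 of 16 higher. That test was therefore not made on unseen genes. Of 18 further glucocorticoid-responsive genes, 12 (66.67 percent, against 24.49 percent of all genes) were called higher and 1 lower, with a median log2 change of 0.80, which only just passes the limit of 66 percent, so a glucocorticoid response in these HD mice may contribute. Map3k6, Txnip and Klf15 rose from 144, 1470.3 and 1164 to 1450.3, 6478 and 3426 (limma adjusted p = 2.4e-06, 2.4e-05 and 8.4e-05). A different time of day could also raise Per1 and other clock genes, but Arntl, Npas2 and Clock had a median of 0.622 and the 6 genes of the opposite arm 0.35, the same sign where a shift in time should give opposite signs; that arm was mixed (Ciart higher by 1.40, Hlf lower by 0.30, Nr1d1 and Per3 not called), so a shift is not excluded. Corticosterone in blood and the hour of death would test both, and illness or handling was not tested.

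Genes lower in HD moved back with WNT5B more often than independent lists do (1624 against 1139.3), while genes higher in HD exceeded them both back (1718 against 1573.7) and further up (1625 against 1350.8), and the tests of this pattern were chosen only after the results were seen. Chance values of the shared HD control libraries could give such a pattern, but the covariance differed from the simulated mean by -0.1755 and lay outside the simulated range, and with the HD controls split it was -0.18 to -0.17. A state shared by the HD control libraries apart from genotype could do the same: their variance was at most 2.09 times that of counting reads, as repeated libraries of 1 sample might be, and no other HD controls exist here, so this cannot be told apart from genotype. WNT5B delivery could move 48.038 percent of the genes back, but there is no HD library of the same preparation without WNT5B to compare. With a weight per group the share was 39.995 percent, against 35.2 for independent lists.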
